A study of Homo sapiens with 6 samples.

How the data were processed

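RNA was sequenced from MH7A, an immortalised line of synovial fibroblasts from a patient with rheumatoid arthritis. Total RNA was extracted with Trizol, ribosomal RNA was removed with biotinylated probes, and the rest was heat-fragmented and primed at random, per the labels' protocols. The strandedness of the counting is not given in the sources used here. The submitters' processing notes name bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma, without saying what each was used for. The notes also name the mouse build mm10, while the samples are labelled human and the table carries human gene symbols. The human build is therefore not given in the sources used here, and no coordinates are printed.

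The deposited table held estimated counts per gene, as whole numbers, for 19475 gene symbols in 6 libraries, and these values entered the tests as deposited, with no rounding needed. Each column name is a sample number given in the labels, and groups were taken from the labels alone. Low values were not spread evenly. Of the values between 1 and 7, 41.8% equalled 4 and 67.2% equalled 4 or 5, with further peaks at 8, 12 and 16. A sequenced fragment therefore appeared to be worth about 4 units of the deposited estimated count. The totals of 86000253 to 108074289 units would then correspond to about 21500063 to 27018572 fragments per library, so the precision is that of the deposited counts divided by about 4. The limit that a count of 0 allows was set at 3 fragments, or 12 units per library (0.111 to 0.140 CPM, the standard count per library scaled to a common total). Floors cover counting error only, since amplified fragments without molecular identifiers are not independent molecules. There were 3523 symbols at 0 in every library, and 12 symbols had been turned into dates by a spreadsheet. No mitochondrially encoded gene was among the symbols.

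The one comparison the labels give, TNF plus LED (n = 3) against TNF (n = 3), was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by TMM, and robust dispersions were fitted with no covariate. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Sample numbers were not shared between the groups, so no pairing was used. CPM values were computed from the TMM-scaled library sizes. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Where all TNF libraries were at 0, the fold was computed against the floor in each library and is given as a lower bound. HSPA1A and HSPA1B are near-identical copies, so the split of counts between them is uncertain, as are counts of genes that overlap a neighbour.

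A set of 31 gene lists was fixed before the data were examined. The 30 lists with at least 5 tested members were tested with camera from limma 3.58.1 at the preset correlation of 0.01, adjusted over the lists. The list of mitochondrially encoded genes had no member in the table. Members past the threshold were counted over all genes tested and adjusted over the list alone. The named genes were also fixed by rule. They were the 10 largest changes in each direction among genes past the threshold with non-overlapping groups and a mean of at least 1 CPM in the higher group. Up to 4 called members with the lowest p came from each list, or the 2 lowest where none was called. IL6, CXCL8, IL1B, CCL2, MMP1, MMP3, MMP13, PTGS2, TNFAIP3, TRPV4 and MKI67 were always named, and XIST and Y-linked genes were left out. A gene named outside this rule is said to have been chosen after its values were seen, and some results for single genes under the rule are not reported here.

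The procedure was tested on simulated counts for 13595 genes, drawn with the means, dispersions and library sizes of these samples and with 200 genes changed. It called 52 of 100 genes changed by 1 on the log2 scale and 95 of 100 changed by 2, with 11 false calls. Genes were drawn independently, with no shift shared by many genes of a library, so these rates may not carry over to the real samples. Libraries were compared in pairs before averaging. Chi-square per degree of freedom lay between 27.8 and 136 within groups, so no library was a copy of another. The alternatives tried were other filters, other scalings, DESeq2 1.42.0, limma-voom, each library left out in turn, other thresholds, and for the lists an estimated correlation and fry. Added after the data were seen were counts divided by 4, removal of both libraries that stood apart, removal of a GC or length trend per library, scaling without the heat shock list, and a floor of 12 counts. GENCODE release 29 supplied gene neighbours, lengths, GC content and exon numbers, and matched 19208 of the 19475 symbols. The labels do not say that the samples are separate cultures, so p-values measure only the spread between these samples, which may be technical.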

Results

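Gene expression was measured by RNA sequencing in MH7A cells, a synovial fibroblast line from rheumatoid arthritis that is used as a model of the inflamed joint lining. All 6 libraries came from cells given TNFα at 10 ng/ml, a cytokine that drives joint inflammation. In 3 of them (replicates 4, 6 and 10) the cells also received red light from a 630 nm LED for 15 min, 3 times, and the other 3 (replicates 2, 8 and 14) had TNFα alone. The comparison asks what differed with LED exposure in TNFα-treated cells. It cannot separate light from any warming by the lamp, since no warmed or sham-exposed group was included. No library without TNFα or with light alone was part of the design, so the effect of TNFα itself was not measured here. Deposited totals were 107139947, 102668851 and 86000253 estimated counts in TNF replicates 2, 8 and 14 and 104438193, 108074289 and 94615430 in LED replicates 4, 6 and 10, and between 14079 and 14943 genes were above 0.

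Cells given TNFα and LED light had far higher transcripts of heat shock proteins and chaperones, and lower transcripts of the cell division and DNA replication machinery, than cells given TNFα alone. The inducible chaperone HSPA1A went from 122 ± 57.8 to 6769 ± 3565 CPM (SD, n = 3 each). Transcripts of several secreted inflammatory and matrix-cleaving proteins were lower, among them the neutrophil chemokine CXCL8 (3.20-fold) and the urokinase PLAU (3.87-fold). The PLAU call held with any single library left out, while that of CXCL8 was lost without LED replicate 4 or 6. Transcripts of other TNFα products that are central to arthritis, including CCL2, MMP1 and MMP3, did not pass the test. IL6, at a log2 fold change of -1.15 ± 0.34, did not pass over all genes but passed with DESeq2. Of 13794 genes tested, 336 were higher and 377 lower with LED at an adjusted p below 0.05, and 256 and 251 of these differed at least 2-fold. For all 713 called genes the libraries of the groups did not overlap, and this held for 32.4% of all tested genes, where chance gives 10% for 3 against 3.

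In the heat shock and chaperone list 23 of 29 members rose, none fell and 6 did not pass, and 26 rose when adjusted over the list alone. The median member rose by 1.92 on the log2 scale (camera adjusted p = 2.7e-65, and adjusted p = 0.338 with an estimated correlation). HSPA6, a strictly stress-inducible member of the HSP70 family, went from 0.904 ± 0.206 to 316 ± 226 CPM, a log2 fold change of 8.45 ± 0.83 (SE, adjusted p = 0.00233). HSPA1A rose by 5.79 ± 0.51 and HSPA1B by 5.61 ± 0.53 on the log2 scale, although the division of counts between these near-identical copies is uncertain. The HSP110 genes HSPA4L (4.50 ± 0.37) and HSPH1 (4.19 ± 0.34), the HSP70 co-chaperone BAG3 (3.40 ± 0.23) and the HSP90 co-chaperone FKBP4 (2.81 ± 0.22) rose as well. DNAJA4, a J-domain co-chaperone of HSP70 outside the list, went from 0.131 ± 0.0975 to 19.7 ± 0.912 CPM (log2 fold change 7.18 ± 0.43, adjusted p = 0.000381). The constitutive HSPA8 was 0.72 ± 0.25 higher without passing over all genes (adjusted p = 0.13), though it passed adjusted over the list alone (0.0201). HSF1, the transcription factor of the heat shock response, had a log2 fold change of -0.05 ± 0.20. HSPA8 and HSF1 were chosen after their values were seen. The list took 1.03% to 1.09% of all counts in the TNF libraries and 4.23%, 5.63% and 3.10% in LED replicates 4, 6 and 10. Between 18 and 23 members stayed called higher with any single library left out. Among 19 alternatives HSPA6 and HSPA1B each lost the call in 1, which was not a single-library omission.

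**Figure D1:**
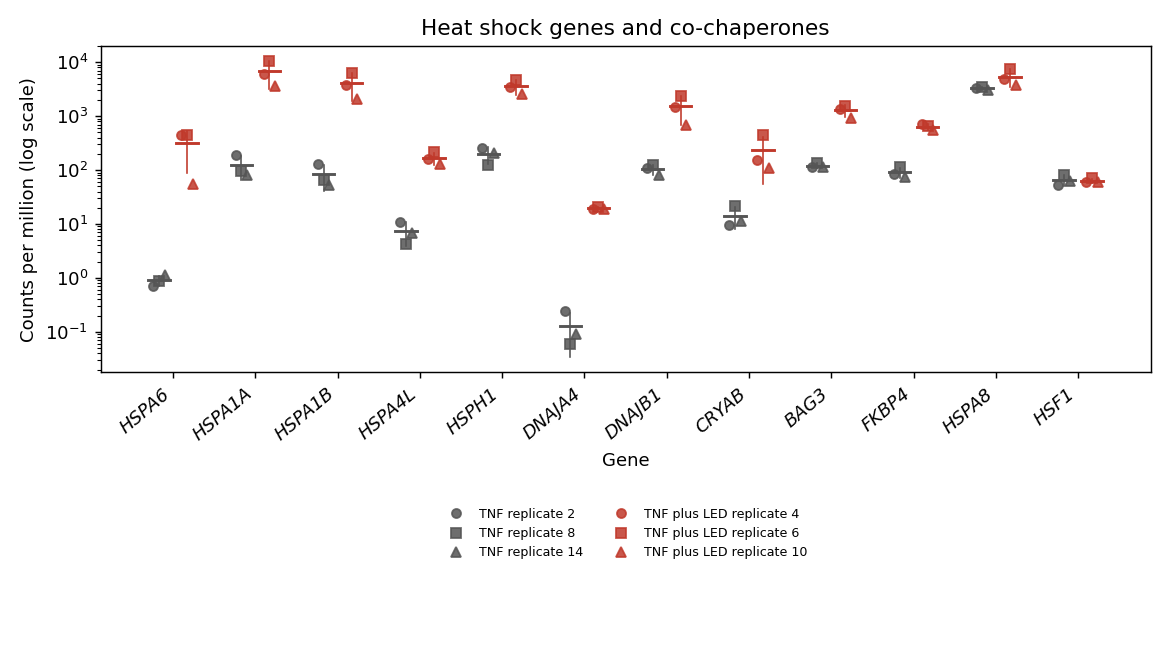
CPM (log axis) of 12 heat shock genes and co-chaperones in each library, with TNF in grey and TNF plus LED in red. Symbols are libraries, horizontal lines are group means and vertical lines are ± 1 SD (n = 3). HSPA6 lies near 1 CPM in all TNF libraries and between 54.9 and 453 CPM with LED, while HSF1 overlaps.

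Known targets of TNFα signalling changed in part. Of 31 tested targets of NF-kB, the transcription factor that TNFα activates, 2 fell, 1 rose and 28 did not pass, with the same counts adjusted over the list alone. ICAM1, an adhesion molecule for leukocytes, fell from 516 ± 130 to 228 ± 10.1 CPM (log2 -1.18 ± 0.21, adjusted p = 0.0222). NFKB2, a subunit of the factor, fell by 0.75 on the log2 scale, and BCL3, a nuclear cofactor of it, rose by 0.97. These calls were lost in most single-library omissions: ICAM1 without TNF replicate 14 or any 1 LED library (up to 0.102), NFKB2 without any library but TNF replicate 2 (up to 0.168) and BCL3 without any library but LED replicate 6 (up to 0.151). The list as a whole did not pass (camera adjusted p = 0.0816, and 0.0381 without TNF replicate 2). TNFAIP3, an inhibitor of NF-kB signalling, had 488 ± 94.0 CPM with TNF and 290 ± 109 with LED (adjusted p = 0.163).

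Among 30 tested cytokines and chemokines 3 fell, 1 rose and 26 did not pass, and 7 fell and 1 rose when adjusted over the list alone. CSF2, which encodes the myeloid growth factor GM-CSF, fell 5.19-fold (62.4 ± 30.9 to 12 ± 0.670 CPM, log2 -2.37 ± 0.33, adjusted p = 0.00926). CXCL8 fell from 2335 ± 529 to 731 ± 192 CPM (log2 -1.68 ± 0.26, adjusted p = 0.0122), and IL1B fell by 1.62 on the log2 scale (adjusted p = 0.0281). LIF, an IL6-family cytokine, rose by 1.68 (adjusted p = 0.0475). It had 33.7, 9.14 and 15.8 CPM in TNF replicates 2, 8 and 14, and its log2 fold change lay between 1.34 and 2.31 across the settings. IL6 itself had 141 ± 50.5 CPM with TNF and 63.5 ± 25.3 with LED, with overlapping groups and an adjusted p of 0.0822 over all genes, though it passed adjusted over the list alone (0.0273), with DESeq2 (0.00773) and with a GC trend removed (0.0382), and its log2 fold change lay between -1.52 and -0.90 in every setting. The monocyte chemokine CCL2 had 111 ± 57.3 and 106 ± 51.1 CPM (adjusted p = 0.949). DESeq2 called 9 members, 8 of them lower, and limma-voom 4. The list passed camera in the lower direction (adjusted p = 0.0122), but not with an estimated correlation (adjusted p = 0.612), without TNF replicate 14 (0.0842) or without LED replicate 6 (0.0571). Its median deviation from the 6-library mean was 0.18, -0.05 and 0.63 in TNF replicates 2, 8 and 14 and -0.42, -0.45 and 0.30 in LED replicates 4, 6 and 10, so the groups overlapped. Without LED replicate 4, 6 or 10 the members that fell numbered 1, 0 and 5, and 2 without TNF replicate 14. Single-library omissions also ended the calls of CSF2 (0.0762 without LED replicate 6), of CXCL8 (up to 0.0738 without LED replicate 4 or 6), of IL1B (up to 0.131 without TNF replicate 14 or LED replicate 4 or 6) and of LIF (up to 0.148 without any library but TNF replicate 2).

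**Figure D2:**
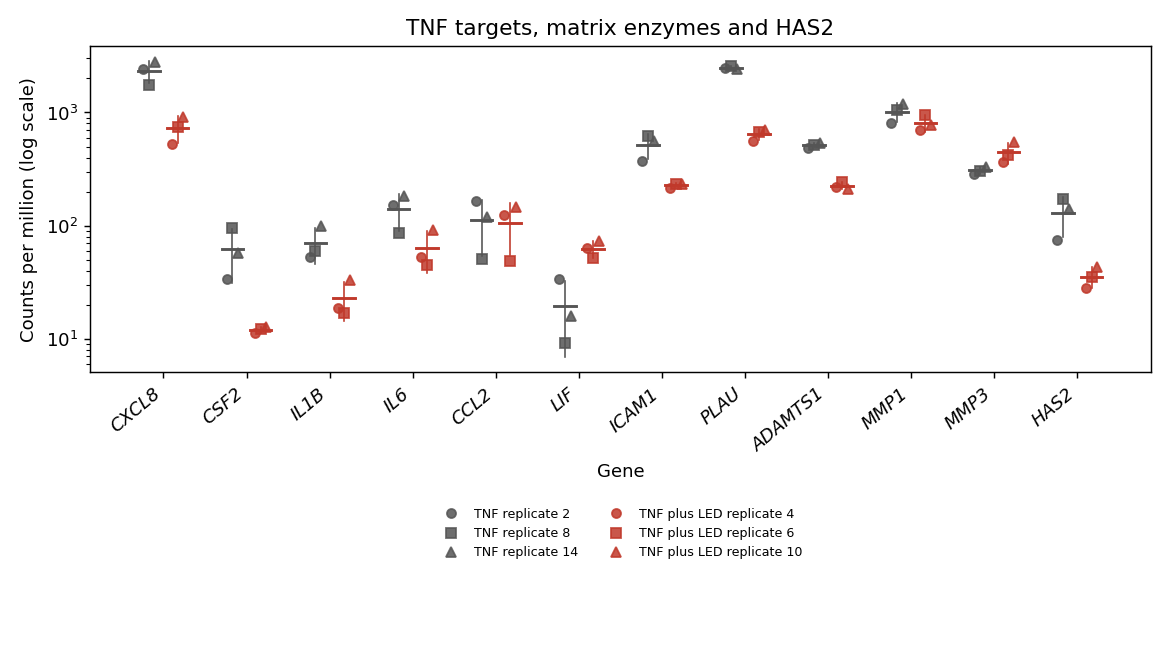
CPM (log axis) of 12 TNFα-related genes, matrix enzymes and HAS2 in each library, with TNF in grey and TNF plus LED in red. Lines are group means and ± 1 SD (n = 3). CXCL8, CSF2, IL1B, ICAM1, PLAU, ADAMTS1 and HAS2 are lower with LED and LIF is higher, while IL6, CCL2 and MMP1 overlap. MMP3 is higher with LED without overlap but did not pass the test.

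Of 31 tested matrix-degrading enzymes and their inhibitors 7 fell, none rose and 24 did not pass, and 8 fell when adjusted over the list alone. PLAU, which activates plasmin at the cell surface, fell from 2496 ± 94.7 to 645 ± 75.9 CPM (log2 -1.95 ± 0.18, adjusted p = 0.00159). PLAT, the other plasminogen activator, fell by 1.13 on the log2 scale, and the aggrecan- and versican-cleaving proteases ADAMTS1 and ADAMTS4 fell by 1.19 and 2.54. The collagenase MMP1 (1016 ± 186 against 809 ± 134 CPM, adjusted p = 0.384) and the stromelysin MMP3 (309 ± 23.5 against 446 ± 92.4 CPM, adjusted p = 0.139) did not pass, and MMP13 was near the detection limit in both groups (0.290 ± 0.351 and 0.269 ± 0.193 CPM). MMP3 leaned higher with LED (log2 0.53 ± 0.19), and its groups did not overlap. The list's median was 0.04 and its mean -0.30, with camera in the lower direction (adjusted p = 0.00571, and adjusted p = 0.493 with an estimated correlation). The members that fell numbered 2 without TNF replicate 14, LED replicate 4 or LED replicate 6. The PLAU call held with any single library left out, whereas ADAMTS1 lost its call without LED replicate 4 (0.0542), ADAMTS4 without TNF replicate 14 or LED replicate 6 (up to 0.0762) and PLAT without TNF replicate 14 or LED replicate 4 or 6 (up to 0.0675).

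Matrix and growth factor genes changed in part. THBS1, a secreted glycoprotein that activates TGF-beta, fell 3.15-fold and the basement membrane collagen COL4A1 fell 1.63-fold. They were the 2 members that fell of 30 tested collagens and matrix proteins (none rose and 28 did not pass, the same counts adjusted over the list alone; camera adjusted p = 0.0224, adjusted p = 0.576 with an estimated correlation, and 0.0726 and 0.0775 without TNF replicate 14 or LED replicate 4). COL4A1 lost its call in each of the 6 single-library omissions (up to 0.217), and THBS1 without LED replicate 6 (0.0732). Of 30 TGF-beta and YAP targets 3 fell, 2 rose and 25 did not pass, against 3 each when adjusted over the list alone (BMP4 the further one, 1.39; camera adjusted p = 0.267). Those that fell were THBS1, CTGF, a matricellular YAP target (log2 -1.64 ± 0.19, adjusted p = 0.00461), and BMP2 (-1.23 ± 0.24), while ID2, a BMP-responsive inhibitor of differentiation, rose by 2.39 ± 0.29 and ANKRD1, a YAP target, by 1.39. ANKRD1 and BMP4 were chosen after their values were seen. CTGF and ID2 stayed called with any single library left out, while BMP2 lost its call without TNF replicate 14 or any 1 LED library (up to 0.108) and ANKRD1 without any library but LED replicate 4 (up to 0.126), and 8, 3, 2 and 3 members were called without TNF replicate 2, TNF replicate 14, LED replicate 6 or LED replicate 10. Among 19 alternatives ID2 lost its call in 1, which was not a single-library omission. Among 29 angiogenic and growth factors PGF (0.168 ± 0.0982 to 2.24 ± 0.25 CPM) and VEGFA (2.32-fold) rose, VEGFC fell 2.13-fold and 26 did not pass, against 2 higher and 3 lower adjusted over the list alone (with FGF5 and PDGFB, chosen after their values were seen; camera adjusted p = 0.825 in the lower direction). The median of this list was -0.05 and its mean 0.04. PGF lost its call without LED replicate 6 (0.0503), VEGFC without any library but TNF replicate 2 (up to 0.125) and VEGFA without any library but TNF replicate 14 (up to 0.143). HAS2, the main hyaluronan synthase of synovial fibroblasts, fell from 129 ± 49.7 to 35.5 ± 7.56 CPM (log2 -1.86 ± 0.31, adjusted p = 0.0162). It was the only member called of 20 synovial fibroblast markers, of which adjusted over the list alone 1 rose (UGDH, chosen after its values were seen) and 1 fell (median 0.04, camera adjusted p = 0.814 in the lower direction). Its call was lost without TNF replicate 14 or LED replicate 4 or 6 (up to 0.104).

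Of 30 tested G2/M genes 20 fell, none rose and 10 did not pass, and 29 fell when adjusted over the list alone. Their median was -1.14 on the log2 scale (camera adjusted p = 9.3e-26, and adjusted p = 0.460 with an estimated correlation). The proliferation marker MKI67 fell from 207 ± 50.7 to 94.2 ± 9.80 CPM (log2 -1.13 ± 0.21, adjusted p = 0.0242), and the spindle genes BUB1, KIF11, KIF23 and NUF2 fell by 1.28, 1.14, 1.17 and 1.13. Among 32 DNA replication and S phase genes 18 fell, none rose and 14 did not pass, and 31 fell adjusted over the list alone, with a median of -1.07 (camera adjusted p = 2.4e-22, and adjusted p = 0.460 with an estimated correlation). E2F1, which activates S phase genes, fell by 1.61 ± 0.30, and POLD1, CDC45 and MCM4 of the replication machinery fell by 1.29, 1.24 and 1.18. IQGAP3, E2F8 and ESPL1, which have roles in proliferation, E2F repression and sister chromatid separation, were among the 10 largest decreases, at -2.16 ± 0.37, -2.08 ± 0.44 and -2.08 ± 0.39. In TNF replicates 2, 8 and 14 IQGAP3 had 22.4, 67.7 and 30.6 CPM, ESPL1 13.1, 36.6 and 16.9 and E2F8 2.87, 3.18 and 3.24. The sizes for IQGAP3 and ESPL1 thus leaned on TNF replicate 8, and their smallest log2 fold changes among the alternatives were -1.50 and -1.31. E2F1 (22.5, 45.0 and 22.0 CPM), POLD1 (27.7, 44.4 and 29.1), CDC45 (18.8, 28.3 and 18.5) and MCM4 (141, 195 and 139) were also highest there. Their smallest log2 fold changes among the alternatives were -1.07, -0.93, -1.01 and -0.83. TNF replicate 8 stood apart from the other TNF libraries: the median G2/M gene there was 0.93 above its 6-library mean on the log2 scale, against 0.18 and 0.47 in TNF replicates 2 and 14. Without that library 17 of the 20 G2/M calls and 14 of the 18 S phase calls were kept, and 2 further G2/M genes were called. The calls were lost almost completely without TNF replicate 14 (0 and 1 called), LED replicate 4 (2 and 0), LED replicate 6 (0 and 0) or LED replicate 10 (1 and 1). The lower direction remained. Both lists passed camera at the preset correlation in each single-library omission (adjusted p up to 5.5e-18 and 1.0e-18, without LED replicate 10). The log2 fold change of MKI67 lay between -1.39 and -0.85 across the settings. In single omissions the adjusted p of MKI67, E2F1, IQGAP3, E2F8 and ESPL1 reached 0.110, 0.122, 0.116, 0.104 and 0.129.

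**Figure D3:**
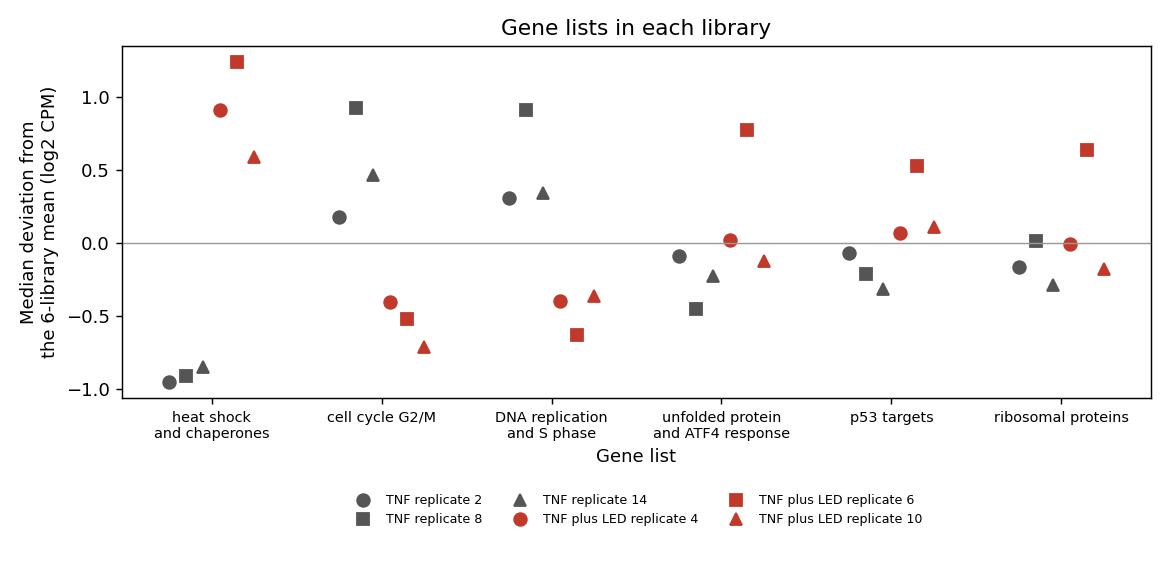
Median over each list of the deviation of log2 CPM from the 6-library mean, for 6 lists (x axis) in each library, with TNF in grey and TNF plus LED in red. The heat shock list separates the groups (-0.95 to -0.85 against 0.59 to 1.24), TNF replicate 8 is highest for both cell cycle lists, and LED replicate 6 is highest for the unfolded protein, p53 and ribosomal lists.

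Of 28 p53 targets 6 rose, none fell and 22 did not pass, and 12 rose when adjusted over the list alone (median 0.54, camera adjusted p = 0.000384, and adjusted p = 0.532 with an estimated correlation). MH7A cells carry a viral large T antigen, which binds p53. Those with the lowest p were the stress kinase PLK2 (1.83-fold), the death receptor FAS (1.87-fold), the glycolysis regulator TIGAR (1.96-fold) and TP53INP1 (2.36-fold). No p53 target stayed called without TNF replicate 14 or without LED replicate 4, 6 or 10, and 3 did without TNF replicate 8. The list was 0.53 above its 6-library mean in LED replicate 6 and 0.07 and 0.11 above it in LED replicates 4 and 10. In single omissions the adjusted p of PLK2, FAS, TIGAR and TP53INP1 reached 0.0939, 0.118, 0.118 and 0.151. FAS was also the only member called of 30 apoptosis genes, over all genes and adjusted over the list alone (camera adjusted p = 0.354, lower direction). Of 15 tested replication-dependent histones 1 rose, HIST1H3D (3.27-fold, adjusted p = 0.0172, and up to 0.0872 without TNF replicate 14 or LED replicate 4 or 6), and 4 rose adjusted over the list alone (also HIST1H2BK, HIST1H4H and HIST2H2BE, chosen after their values were seen; median 0.77, camera adjusted p = 0.00293, and adjusted p = 0.522 with an estimated correlation). The list was 0.73 above its 6-library mean in LED replicate 6, 0.33 above it in LED replicate 4 and -0.01 from it in LED replicate 10, and passed camera without LED replicate 6 (0.0220).

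Stress genes outside the heat shock list rose in smaller numbers. Of 30 unfolded protein and ATF4 response genes 2 rose and 28 did not pass, against 8 higher and 1 lower (CHAC1, chosen after its values were seen) adjusted over the list alone. HSPA5, the main chaperone of the endoplasmic reticulum, rose from 1389 ± 194 to 4515 ± 2571 CPM (log2 1.7 ± 0.35, adjusted p = 0.0323), and its co-chaperone DNAJB9 rose by 1.87 ± 0.33. LED replicate 6 carried much of this list: its median deviation was 0.77, against 0.02 and -0.12 in LED replicates 4 and 10. The camera adjusted p was 0.00117, 0.0915 without LED replicate 6, and with an estimated correlation the adjusted p was 0.612. Both genes lost their calls without TNF replicate 8 or 14 or LED replicate 6, and HSPA5 also without LED replicate 4 (up to 0.0883). Of 31 NRF2 and antioxidant genes HMOX1, which degrades heme, rose from 23.8 ± 8.29 to 103 ± 48.0 CPM and OSGIN1 rose 2.71-fold, with 29 not passing and the same counts adjusted over the list alone (median 0.32, camera adjusted p = 0.00213, and adjusted p = 0.576 with an estimated correlation). This list was 0.35 above its 6-library mean in LED replicate 6 and 0.06 and 0.04 above it in LED replicates 4 and 10. HMOX1 lost its call without TNF replicate 14 or LED replicate 4 or 6 (up to 0.118), and OSGIN1 without these or TNF replicate 8 (up to 0.133). Of 30 immediate early and MAPK feedback genes the nuclear receptor NR4A1 (3.31-fold) and EGR3 (0.0251 ± 0.0218 to 0.422 ± 0.0645 CPM) rose and 28 did not pass, against 11 higher and 1 lower (DUSP6, chosen after its values were seen) adjusted over the list alone (median 0.45, camera adjusted p = 0.00325, and adjusted p = 0.493 with an estimated correlation). The median deviation of this list was 0.44, 0.03 and 0.10 in LED replicates 4, 6 and 10 and 0.03 in TNF replicate 8. EGR3 lost its call in each single-library omission (up to 0.143) and NR4A1 without TNF replicate 14 or LED replicate 4 or 6 (up to 0.132).

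Few candidate light and calcium sensors passed the test over all genes. Of 29 TRP channel and calcium entry genes 1 fell, ITPR3, an endoplasmic reticulum calcium channel (1.84-fold), and 28 did not pass, against 2 higher (TRPV1 and CACNA1G) and 3 lower (with TRPV2 and TRPM4) adjusted over the list alone, the further genes chosen after their values were seen. At an unadjusted p below 0.05 were 14 members, 11 of them lower, and DESeq2 called 7 and limma-voom 2. The median of the list was -0.35, and it missed the threshold (camera adjusted p = 0.0540, 0.0132 without TNF replicate 8 and 0.0493 without LED replicate 10). TRPV4, a channel gated by warmth and osmotic stress, had 5.70 ± 1.04 and 5.12 ± 1.52 CPM (adjusted p = 0.784). Of 19 opsin and clock genes only the clock repressor BHLHE40 rose (2.23-fold), with 1 higher and 1 lower (PER1, chosen after its values were seen) adjusted over the list alone (median -0.01, mean 0.12, camera adjusted p = 0.788 in the higher direction). The insulin receptor substrate IRS2 (1.98-fold lower) was the only member called of 31 PI3K-AKT-mTOR genes, over all genes and adjusted over the list alone (camera adjusted p = 0.354). PTGES3, an HSP90 co-chaperone also known as a prostaglandin E synthase, rose 2.08-fold and was the only member called of 10 prostaglandin and nitric oxide enzymes, likewise adjusted over the list alone (camera adjusted p = 0.149). PTGS2, the inducible cyclooxygenase, had 10.2 ± 5.92 and 10.9 ± 1.31 CPM (adjusted p = 0.913). VEGFA was the only member called of 30 hypoxia and glycolysis genes in both counts (median 0.05, camera adjusted p = 0.970 in the lower direction). Every call of this paragraph was lost in at least 3 of the 6 single-library omissions: ITPR3 and IRS2 without TNF replicate 14 or any 1 LED library (up to 0.136 and 0.0773), BHLHE40 without TNF replicate 8 or 14 or LED replicate 4 or 6 (up to 0.116), PTGES3 without TNF replicate 14 or LED replicate 4 or 6 (up to 0.0817) and VEGFA without any library but TNF replicate 14 (up to 0.143).

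No member passed edgeR's test in 6 lists of housekeeping, metabolic or interferon genes, or adjusted over the list alone. These were 32 interferon-stimulated genes (5 at an unadjusted p below 0.05, 2 called by DESeq2 and 0 by limma-voom; camera adjusted p = 0.153, and 7.2e-05 without TNF replicate 2), 30 cholesterol genes (4, 4 and 0), 30 autophagy and lysosome genes (3, 2 and 0; 0.535), 35 ribosomal proteins (0, 0 and 0), 30 cytochrome c oxidase genes (0, 0 and 0; 0.814) and 30 other oxidative phosphorylation subunits (0, 0 and 0; 0.948, with a median of 4.9e-05 and a mean of 0.01 but a test in the lower direction). The interferon list leaned lower in both of its camera tests, with a median log2 fold change of -0.29. Of its 5 members at an unadjusted p below 0.05, 3 were lower and 2 higher. IRF9 and IFIT2 of the interferon list, ACAT2 and LSS of the cholesterol list, and TFEB and MAP1LC3B of the autophagy list had the lowest p, with log2 fold changes of 0.75, 0.74, -0.62, -0.60, 0.83 and 0.56. COX7A2L, COX19 and ATP5PB of the mitochondrial lists were at 0.94, 0.30 and 0.24, the first of them at 0.14 without LED replicate 6. The ribosomal list passed camera in the higher direction (adjusted p = 0.00378, median 0.34), with RPS23 and RPS6 at 0.48 and 0.47, but not without LED replicate 6 (0.638) or with an estimated correlation (adjusted p = 0.777). Its median deviation was 0.64 in LED replicate 6 and -0.01 and -0.18 in LED replicates 4 and 10. The cholesterol list passed in the lower direction (adjusted p = 0.0319, with a median deviation of 0.13 in LED replicate 10 and 0.12 in TNF replicate 14), but not without TNF replicate 2 (0.0528), TNF replicate 8 (0.0844) or LED replicate 6 (0.287), or with an estimated correlation (adjusted p = 0.612).

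**Figure D4:**
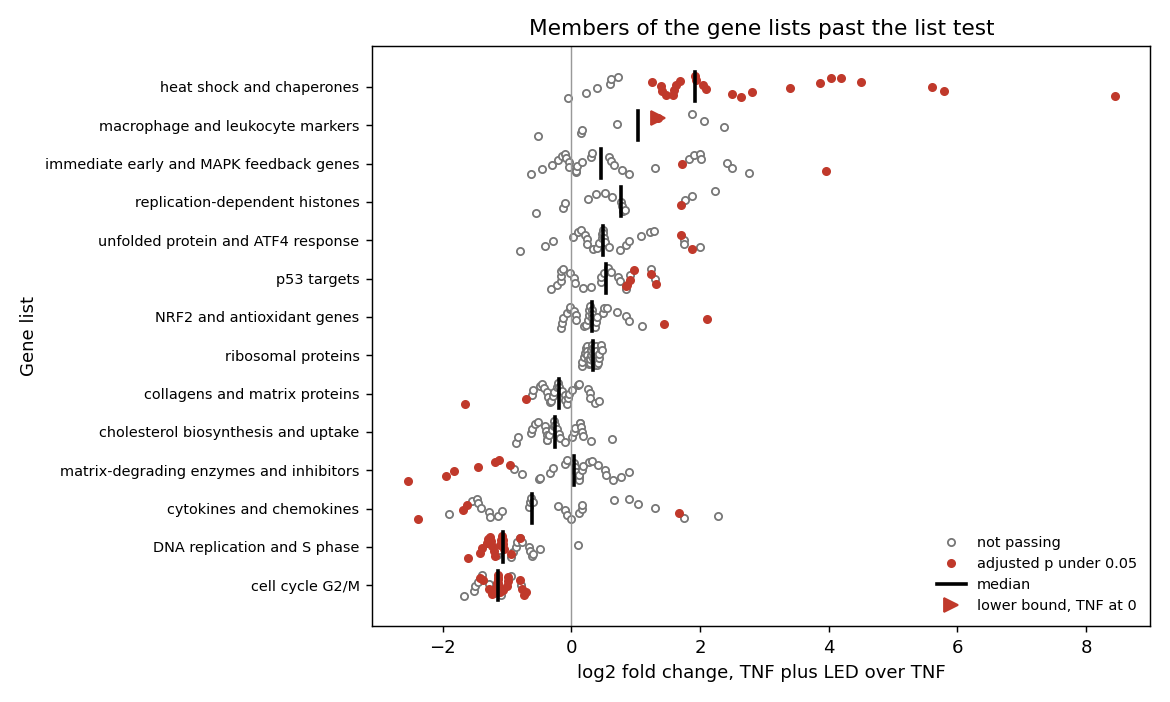
log2 fold change (TNF plus LED over TNF, x axis) of every tested member of the 14 lists past the camera test at its preset correlation. Filled points passed the gene test, open points did not, bars are list medians, and the triangle is a lower bound for MRC1, which was at 0 in all TNF libraries. Heat shock genes reach 8.45, while both cell cycle lists lie almost wholly below 0.

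Few markers of other cell types passed the test. Of 8 tested macrophage and leukocyte markers MRC1, a macrophage lectin, was called higher, at 0 in all TNF libraries and 0.309 ± 0.169 CPM with LED, at least 2.54-fold above the floor (adjusted p = 0.0322). The list passed camera (adjusted p = 0.0349, adjusted p = 0.493 with an estimated correlation, and 0.0646, 0.0836 and 0.0594 without TNF replicate 2, LED replicate 6 or LED replicate 10). Its median was 1.30 as fitted and 1.03 with MRC1 at its bound, and its median deviation was -0.72, -0.95 and -0.05 in TNF replicates 2, 8 and 14 and 0.74, 0.68 and 0.51 in LED replicates 4, 6 and 10. PLVAP was the only member called of 11 endothelial markers, at 0 in all TNF libraries and at least 7.21-fold above the floor with LED (0.226, 2.07 and 0.332 CPM in LED replicates 4, 6 and 10; list camera adjusted p = 0.714). Of 8 epithelial markers none passed edgeR's test, 1 rose adjusted over the list alone (ST14, 0.0262 ± 0.0455 to 0.540 ± 0.172 CPM, adjusted p = 0.0652), 1 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 1 each (list camera adjusted p = 0.224). KRT17 of that list had 0.0888 ± 0.0651 and 0.276 ± 0.198 CPM. The endothelial and leukocyte lists held 1 called gene each over all genes and adjusted over the list alone. PLVAP lies within 50 kb downstream of BST2, an expressed gene on the same strand. MRC1 kept its call only without TNF replicate 2 (otherwise up to 0.145), and PLVAP lost it without TNF replicate 8 or 14 or LED replicate 6 (up to 0.125).

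Several of the largest changes were genes almost silent with TNFα alone. DHDH, NEFM and DGKB had no counts in any TNF library and reached 1.98 ± 0.931, 1.2 ± 0.547 and 1.12 ± 0.442 CPM with LED, at least 16.3-, 9.85- and 9.25-fold above the floor of 12 units per library. LCN10, ALOXE3 and SLC8A2 went from under 0.1 to 1.88 ± 0.264, 3.64 ± 0.315 and 6.64 ± 7.45 CPM. The SLC8A2 mean leaned on LED replicate 6, with 1.94, 15.2 and 2.74 CPM in LED replicates 4, 6 and 10. DHDH, LCN10 and ALOXE3 stayed called in each single-library omission. NEFM and DGKB lost the call without LED replicate 6 (0.0583 and 0.0646), and SLC8A2 without TNF replicate 2 or 14 or LED replicate 6 (up to 0.0867). DHDH lies within 50 kb downstream of NUCB1, an expressed gene on the same strand. Besides genes named above, the largest decreases were PTGES3L-AARSD1 (log2 -3.44 ± 0.72), a readthrough locus whose counts overlap those of its parent genes and are uncertain, NACAD (-2.70 ± 0.35), SYNPO2L (-2.28 ± 0.31), MEOX2 (-2.09 ± 0.49) and KCTD4 (-2.03 ± 0.37). NACAD and SYNPO2L lost the call without LED replicate 6 (0.0574 and 0.0597), KCTD4 without TNF replicate 14 or LED replicate 6 or 10 (up to 0.105), PTGES3L-AARSD1 without TNF replicate 14 or any 1 LED library (up to 0.116) and MEOX2 without any library but TNF replicate 8 (up to 0.145).

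Of the 30 lists tested, 8 passed in the higher and 6 in the lower direction at the preset correlation, and none with an estimated correlation (lowest adjusted p 0.338, with 3 lists at an unadjusted p below 0.05) or with fry (lowest 0.0604, with 10 lists). The count of called genes depended on which libraries were kept: 713 with all, 737, 542 and 113 without TNF replicates 2, 8 and 14, 116, 80 and 219 without LED replicates 4, 6 and 10, and 1669 without both TNF replicate 8 and LED replicate 6. In every one of the 6 omissions 59 of the 713 genes stayed called, 44 higher and 15 lower, and 18 of them were heat shock list members. With a length trend removed per library the balance moved from 336 higher and 377 lower to 398 and 678.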

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

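Removal of the 2 libraries that stood apart, the GC and length trends, counts divided by 4, scaling without the heat shock list and the floor of 12 counts were chosen after seeing the data, and the floor removed no tested gene. All directions of the 68 called named genes were kept in the 1271 fits that tested them, and 208 of these fits no longer passed. Of 410 fits of the 22 uncalled named genes 18 passed and 8 changed sign. Pseudocount, quantile, median-centring and no-trend alternatives were not run, since the table held counts.

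The 713 called genes (336 higher, 377 lower) ranged from 80 to 737 (59 to 314 higher, 21 to 423 lower) with 1 library left out, and the 14 lists from 9 to 14. They became 457 (194 higher) with at least 10 CPM in 3 libraries, which tests fewer genes, 1753 (874 and 879) with DESeq2, 1669 (763 and 906) without TNF replicate 8 and LED replicate 6, 1338 (836 lower) without the GC trend and 1076 (678 lower) without the length trend; for these last 4 the cause was not tested. DESeq2 kept all 713 genes. An adjusted p under 0.1 gave 1471 (695 and 776), under 0.01 gave 70 (53 and 17), and a change of at least 1 on the log2 scale left 251 lower. No list passed with an estimated correlation (0) or fry (0), and the cause was not tested. Other scalings, limma-voom, no filter and counts divided by 4 gave 591 to 809 genes. Depth of about 21500063 to 27018572 fragments limits genes under 1 CPM, which made up 40 of the called genes.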

Other observations

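Tests chosen only after the result was seen were those of TNF replicate 8, of the splits of the libraries, of the J-domain family, of the homologous recombination genes, of the mean number of detected genes after thinning and of the single-exon genes against the histone median, and the lists of proteasome, recombination and hyaluronan genes were drawn up after the largest changes were known. Of 26 homologous recombination and Fanconi genes, which repair DNA breaks and crosslinks, 9 fell with LED, none rose and 17 did not pass, and 19 fell adjusted over the list alone (median log2 fold change -0.86, camera adjusted p = 4.8e-14, and adjusted p = 0.0801 with an estimated correlation). Of these, FANCD2 and FANCI fell by 1.34 and 1.03 on the log2 scale. FANCD2 lost its call without TNF replicate 14 or LED replicate 6 (up to 0.0542) and FANCI without these or LED replicate 4 (up to 0.0736), and 14, 1, 2, 0 and 4 members were called without TNF replicate 8, TNF replicate 14 or LED replicate 4, 6 or 10. With 9 of 26 called, neither bound set for the test was met, so whether the group fell along with the replication genes stayed open. Of 14 genes for hyaluronan synthesis and turnover 3 fell and none rose, against 3 lower and 1 higher adjusted over the list alone (median -0.11, camera adjusted p = 0.0895). Those that fell were HAS2, CEMIP, which binds and helps degrade hyaluronan (503 to 148 mean CPM, log2 -1.76 ± 0.19), and TMEM2, a cell-surface protein linked to hyaluronan breakdown (-1.06 ± 0.22). The call of CEMIP held in each of the 6 single-library omissions, while TMEM2 lost its call without TNF replicate 2 or 14 or LED replicate 4 or 6 (up to 0.135) and HAS2 without TNF replicate 14 or LED replicate 4 or 6 (up to 0.104).

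None of 34 proteasome subunits was called by edgeR (1 had an unadjusted p below 0.05, 1 was called by DESeq2 and 0 by limma-voom). Their median log2 fold change was 0.0787, against 1.92 for the heat shock list, which argues against a rise of the proteasome by about as much as the chaperones. Of all 41 tested genes with DNAJ symbols, the J-domain family, 7 were called higher (DNAJA1, DNAJA4, DNAJB1, DNAJB2, DNAJB4, DNAJB9 and DNAJC24), 1 lower (DNAJC9) and 33 did not pass, with a median log2 fold change of 0.13 (quartiles -0.09 and 0.70), which argues against a rise of the whole family. The calls of DNAJA1, DNAJA4 and DNAJB1 held in each single-library omission, while those of DNAJB2, DNAJB4, DNAJB9, DNAJC24 and DNAJC9 did not (up to 0.163, 0.101, 0.0655, 0.112 and 0.118). Single-exon genes outside the histone and heat shock lists had a median log2 fold change of 0.0483 over 198 genes, against -0.01 for multi-exon genes matched on level (middle 95% of 10000 draws between -0.09 and 0.06), with 9 called higher, 7 lower and a camera p of 0.998. The bound set beforehand, a median at or below that of the matched genes, was not met. The median lay 0.723 below the histone median of 0.77, more than the SD of 0.639 and the quartiles (-0.34 and 0.32) span, which argues against a rise of intronless genes as a class by about as much as the histones. Whether they rose by less stays open.

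The rise of heat shock genes was not accounted for by GC content or by reads shared between near-identical copies. With a GC trend removed per library all 23 members called higher kept their calls and 24 were called. All 23 also kept them with library sizes and scaling computed without the list. The list took at most 5.63% of the counts of any library. This rescaling could therefore move fold changes only slightly, and its result decides nothing. The 18 members outside the HSP70, HSP90, HSP60 and HSP10 families, whose near-identical copies share reads, had a median log2 fold change of 1.61 (quartiles 0.77 and 2.73), with 13 called higher. A hypothesis is that the LED exposure itself may have set off a heat shock response. Light and any warming of the dish by the lamp come together in this design, with no warmed or sham-exposed group, so which of them acted was not tested.

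More genes were detected with LED: between 14594 and 14943 above 0, against 14079 to 14452 with TNF. After every library was thinned to 21500063 fragments the lowest LED library still exceeded the highest TNF library by 177 genes, just under the bound set beforehand, the larger group SD of 178. The group means after thinning, 14676 ± 152 with LED and 14208 ± 178 with TNF, differed by 468 genes, against 495 before, which argues against depth as the whole cause and leaves open a part. Of 4408 genes at 0 in all TNF libraries, 29 reached 12 units in every LED library, while 1 gene showed the converse (C5AR2, chosen after its values were seen). Of these 29 genes, 55.2% had an expressed gene (at least 10 CPM) on the same strand within 50 kb upstream, against 12.3% of 4181 other silent genes (Fisher's exact p = 4.5e-08, two-sided). Most genes silent with TNF were at 0 in every library (3523 symbols), and no downstream share was given for them. The Fisher comparison therefore cannot separate run-on from lying near expressed genes. Within 50 kb downstream 27.6% of the 29 genes had such a neighbour. Only an upstream neighbour was present for 10 genes and only a downstream one for 2 (exact binomial p = 0.0386, two-sided). A hypothesis for this direction is that some of the signal was transcription that ran on from the upstream gene.

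Cell cycle and replication genes were lower with LED by a median of -1.11 over both lists (quartiles -1.25 and -0.88). The median was -0.84 without TNF replicate 8, the TNF library that stood apart, -1.20 with a GC trend removed and -1.20 with a length trend removed, so none of these accounts for the whole decrease. The members called lower numbered 38, and 33, 50 and 52 under those settings, some of them new calls. A biological hypothesis, that the cells may have divided less after LED exposure, was not tested beyond transcripts. Differences in culture density between the samples remain open, since the labels do not give it.

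The split of the 6 libraries by treatment called 713 genes and the highest of the other splits called 1, with 1 of 10 splits giving as many genes. The 10 splits are too few for a share below 0.05.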
